A study of Mus musculus with 180 samples.

How the data were processed

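RNA was measured in the hippocampus of 30 male mice, with 6 libraries per mouse and 180 in all, as the labels give them. A library came from the Camk2a capture (HA-tagged Rpl22 in Camk2a-cre neurons), the pS6 capture or the Input, each in a cytosolic (supernatant) and a membrane (pellet) fraction. Per the labels, mice were in NoCFC Sleep (8), NoCFC SD (7), CFC Sleep (8) and CFC SD (7) groups. The length of the sleep deprivation is not in the labels. Libraries were made with SMART-seq v4 per the labels, and the submitters' processing notes name the genome build GRCm38.p6, STAR 2.6.1a, featureCounts with no version, and MultiQC 1.6a0, without settings. The deposited table holds a count per gene and library for 54429 genes, with whole numbers and no normalization. Total counts per library averaged 20.8, 18.8, 20.4, 17.8, 18.2 and 17.1 M (mega-counts) in Camk2a, pS6 and Input, cytosolic before membrane in each. Depth limits the precision of genes with few counts, and reads without molecular identifiers are not independent molecules.

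Per the extract protocol each fraction of a homogenate was divided into Input and both captures, and libraries with the same number in their titles were taken as those of the same mouse. The pairing was checked on the counts: after removal of group means, the correlation of 2 libraries of the same number had a median of 0.167, against -0.00771 for different numbers, and in 249 of 450 cases a library's closest match in another library type had its own number. No pair of libraries in a group was a copy (lowest chi-square per degree of freedom 3.21). Mouse numbers form runs, 1 to 11, 12 to 22 and 23 to 30, and training and run coincide in the first 22 mice. With the run as a term, CFC is estimated from mice 23 to 30 alone.

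Each library type was fitted on its own with edgeR 4.0.16 under R 4.3.3, with limma 3.58.1 and statmod 1.5.0: genes kept by filterByExpr, TMM scaling, a model of the 4 groups, robust quasi-likelihood dispersion and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SD and CFC effects average over the other factor. Fraction and capture comparisons fitted both kinds of library together and needed a fold of 2 besides. Their main fit, also for the interactions with fraction, did not use the pairing of libraries by mouse. The numbers of genes tested were 14836, 14968, 16485, 16637, 15948 and 15642 in the 6 types. At an unadjusted p under 0.05 chance alone gives about 742, 748, 824, 832, 797 and 782 of them. Log2 fold changes and standard errors come from the same models, CPM values carry a prior count of 2 where logged, and mice were counted as above or below the median of the other condition's mice within the same arm of the other factor. An effect in one capture and not in another was not compared across captures, whereas training by sleep, fraction by SD and fraction by CFC were tested as interactions.

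The 37 gene lists were written before the data were examined, as were the comparisons, the named-gene rule and the alternatives other than those given below as later. They cover activity-regulated genes, cytosolic heat shock, ER chaperones, the integrated stress response, clock genes, cold-inducible genes, glucocorticoid targets, large and small ribosomal proteins, translation factors, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, the proteasome, glutamate and GABA receptors, postsynaptic scaffold, synaptic vesicle, synaptic adhesion, voltage-gated channels, neuropeptides and secreted proteins, cholesterol synthesis, cytoskeleton, long noncoding RNAs, chromatin modifiers, and markers of excitatory, inhibitory, dentate granule, CA1 and CA3 or CA2 neurons and of astrocytes, oligodendrocytes, precursors, microglia, vascular cells, choroid plexus and blood. Each list was tested with camera at a preset correlation of 0.01 on voom values, and again with an estimated correlation, and with fry. For the SD and CFC effects in captured types the 6 genes higher and 6 lower with the largest change, at an average log2 CPM of at least 3, may be named; in Input 3 and 3; for fraction and capture comparisons 5 and 5; for interactions the 3 with the smallest p each way. Predicted genes were passed over, and members of the lists, Camk2a, Rpl22, Rps6, Cirbp and Rbm3 may be named whatever their result.

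Gene positions are from GENCODE vM21 on GRCm38, in which 53851 of the 54429 symbols (98.9%) were found, and 196 of 199 named genes had 1 position. Of these, 58 have exons that overlap another gene, among them Bdnf, Dbp, Cdkn1a, Rbm3, Manf, Malat1, Meg3, Snhg11 and Dync1h1. The strand used in counting is not stated, so counts of such genes are uncertain.

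The methods were tested on simulated data, drawn with the mean and dispersion of each gene in the libraries and with added changes. The draws held no differences between number runs or between odd and even mouse numbers, so these rates may not carry over to the data. For SD in cytosolic Camk2a, 76.1% of genes changed 1.3-fold, 88.1% of those changed 1.5-fold and 93.9% of those changed 2-fold were recovered, with 6 false calls among 14836 genes. For CFC in membrane Camk2a the shares were 56.7%, 91% and 93.9%, and 25.4%, 55.2% and 74.2% with the run as a term. For the fractions all 200 genes changed 3-fold were recovered. The alternatives were DESeq2 1.42.0, RLE in place of TMM, limma-voom with sample quality weights, no low-count filter, the mouse as a block where a mouse gave both libraries, the number run as a term, and an estimated correlation for lists. Odd or even mouse number as a term, the number run by fraction as a term for the interactions with fraction, the number run with an estimated correlation for lists, and leaving out mouse 22 were chosen after seeing the data. For every result, other splits of the mice were drawn, 100 each and 50 for comparisons of library types. The first draw had 50 and 30, and the number was raised after it was seen, with no verdict changed. The values of some single genes are not reported here, though these genes stayed in the tests and in the counts of the lists.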

Results

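RNA was sequenced from the hippocampus of 30 male mice carrying an HA-tagged ribosomal protein, Rpl22, in neurons with an active Camk2a promoter. Each mouse gave 6 libraries. RNA bound to the tagged ribosomes (Camk2a), RNA bound to ribosomes with phosphorylated ribosomal protein S6 (pS6), a mark of recently active neurons, and RNA without capture (Input) were each taken from a cytosolic and a membrane fraction of the tissue. The mice were trained by contextual fear conditioning (CFC) or stayed in the home cage (NoCFC), and then slept freely (Sleep) or were deprived of sleep (SD). The groups held 8 NoCFC Sleep, 7 NoCFC SD, 8 CFC Sleep and 7 CFC SD mice. Total counts per library ranged from 12 to 27 M (mega-counts) over the 180 libraries, with a mean of 18.8 ± 3.04 M (SD, n = 180). The labels name no batch, but mice 1 to 11 were all NoCFC, mice 12 to 22 were all CFC, and mice 23 to 30 held 2 mice of each group. These runs of mouse numbers are treated as possible batches. Gene values are log2 fold changes with standard errors, and a gene is said to have risen or fallen only where it passed the test at its adjusted threshold.

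The question of the capture comparison is which cells each antibody drew RNA from. In the cytosolic fraction the Camk2a capture held less RNA of inhibitory neurons and glia than Input did, and more of some pyramidal-cell genes (30 mice in each). Of 24 inhibitory-neuron genes, 22 were lower, with Sst at -3.78 ± 0.07, Npy at -4.17 ± 0.07 and Pvalb at -4.24 ± 0.07. All 20 oligodendrocyte genes, all 19 microglial genes, 11 of 11 genes of oligodendrocyte precursors and 22 of 23 astrocyte genes were lower as well, among them Cx3cr1 at -3.79 ± 0.08, Gja1 at -4.06 ± 0.07 and Mbp at -2.24 ± 0.04. The inhibitory-neuron and these 4 glial lists passed also with an estimated correlation (adjusted p = 0.0226 for each). Lower still were Bc1, a small noncoding RNA, at -7.53 ± 0.13, and all 9 mitochondrially encoded genes, with mt-Cytb at -6.45 ± 0.07 (adjusted p = 0.0588 with an estimated correlation). Of 11 CA1 pyramidal genes, 4 were higher (adjusted p = 0.0968 with an estimated correlation), including Wfs1 at 1.36 ± 0.07 and Nov at 1.11 ± 0.06. Other genes higher in the capture were Sh3pxd2a at 1.72 ± 0.08, Efcab6 at 1.49 ± 0.07 and Rasd1 at 1.28 ± 0.05. Camk2a itself was at 0.74 ± 0.04, short of the fold of 2 that a call needed. In total 59 genes were higher and 2714 lower among 16421 tested.

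In the membrane fraction the Camk2a capture held less of 19 of 24 inhibitory-neuron genes, 21 of 23 astrocyte genes, 19 of 20 oligodendrocyte genes and all 19 microglial genes (adjusted p = 0.0844 with an estimated correlation for each). It held less of 11 of 11 genes of oligodendrocyte precursors too (adjusted p = 0.0676 with an estimated correlation). Sst was at -1.56 ± 0.06 and Gja1 at -2.18 ± 0.06. Of 11 CA1 genes, 6 were higher (adjusted p = 0.0676 with an estimated correlation), and the genes with the largest rise were Hipk4 at 1.77 ± 0.06 and Lmtk3 at 1.76 ± 0.10. Malat1, a nuclear long noncoding RNA, was at -3.75 ± 0.13. In total 303 genes were higher and 2703 lower. No test was made of the difference between the fractions.

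The pS6 capture was richer than Input in activity-regulated genes. In the cytosolic fraction 18 of 47 were higher and 1 lower (adjusted p = 0.515 with an estimated correlation), among them Fosb at 2.77 ± 0.09, Inhba, an activin subunit, at 2.09 ± 0.06, the neurotrophin gene Bdnf at 1.52 ± 0.04 and Fos at 1.42 ± 0.09. In the membrane fraction 13 of 47 were higher (adjusted p = 0.153 with an estimated correlation). Nav1, a neuron navigator gene, was at 3.18 ± 0.05 in the cytosolic and 2.68 ± 0.08 in the membrane fraction. Of 20 oligodendrocyte genes 19 were lower in the cytosolic pS6 capture, as were 11 of 23 astrocyte and 10 of 19 microglial genes, whereas of 24 inhibitory-neuron genes 2 were higher and 3 lower. Blood genes also came down with pS6: 4 of 5 were higher in the cytosolic fraction, and Hbb-bs, a haemoglobin gene, was at 2.68 ± 0.10 in the membrane fraction. In total 1952 genes were higher and 1519 lower in the cytosolic fraction, and 1232 higher and 625 lower in the membrane fraction.

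Set directly against the Camk2a capture, the cytosolic pS6 capture held more of 19 of 24 inhibitory-neuron genes (adjusted p = 0.117 with an estimated correlation), with Pvalb, the parvalbumin gene, at 6.09 ± 0.07 and Sst at 3.71 ± 0.08. It also held more of 20 of 23 astrocyte and 18 of 19 microglial genes (adjusted p = 0.401 and 0.308 with an estimated correlation) and of 20 of 27 long noncoding RNAs (adjusted p = 0.0325 with an estimated correlation). Of 13 dentate granule genes 10 were lower, with Plk5 at -2.63 ± 0.07, and of 11 CA1 genes 5 were lower, with Wfs1 at -2.17 ± 0.07 (adjusted p = 0.308 and 0.4 with an estimated correlation). Bcar1, Trip11 and Cobl were at -2.64 ± 0.05, -2.36 ± 0.06 and -2.19 ± 0.11. Hba-a1 was at 5.93 ± 0.18 and Ttr, a choroid plexus transcript, at 5.27 ± 0.75. In total 3735 genes were higher and 1392 lower. In the membrane fraction 2793 were higher and 237 lower, including 16 of 24 inhibitory-neuron genes and 13 of 23 astrocyte genes.

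The fraction comparison asks which transcripts sat on membranes. Transcripts of mitochondria, of secreted proteins and of membrane proteins were higher in the membrane fraction (30 mice in each). In the Camk2a capture all 43 synaptic adhesion genes were higher, 24 of 25 glutamate receptor genes, 12 of 14 GABA receptor genes, 44 of 52 voltage-gated channel genes, 26 of 28 genes of neuropeptides and other secreted proteins, and 24 of 26 genes of endoplasmic reticulum (ER) chaperones. Examples are the AMPA receptor subunit Gria2 at 1.39 ± 0.05, the NMDA receptor subunit Grin2b at 2.23 ± 0.05, Sst at 4.21 ± 0.09 and the chaperone Hspa5 at 1.78 ± 0.07. Sst is an inhibitory-neuron gene, and its deficit in this capture against Input was smaller in the membrane than in the cytosolic fraction. Its value therefore does not show location within Camk2a neurons alone. All 9 mitochondrially encoded genes were higher, with mt-Nd4 at 6.65 ± 0.07 and mt-Rnr2 at 6.61 ± 0.07. Of 20 cholesterol synthesis genes 10 were higher. With an estimated correlation the adjusted p was 0.192 for adhesion genes and channels, 0.141 for glutamate receptors, 0.238 for GABA receptors, 0.135 for secreted proteins, 0.242 for ER chaperones and cholesterol synthesis, and 0.196 for mitochondrial genes.

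Of 31 proteasome genes 6 were lower in the membrane fraction of the Camk2a capture (adjusted p = 0.242 with an estimated correlation), and Neurod6, a transcription factor gene of pyramidal cells, was at -1.57 ± 0.03. The genes with the largest fall were Clvs1 at -2.16 ± 0.04, Jazf1 at -1.92 ± 0.04, Klhl11 at -1.87 ± 0.07, Lin7c at -1.86 ± 0.06 and Fyttd1 at -1.84 ± 0.04. None of the 46 large and 33 small ribosomal protein genes changed by a factor of 2, with list medians of -0.21 and -0.1. All 23 astrocyte, all 19 microglial and 19 of 24 inhibitory-neuron genes were higher in the membrane fraction of this capture, with Gja1 at 5.14 ± 0.08 (adjusted p = 0.196, 0.242 and 0.196 with an estimated correlation). In the pS6 capture 39 of 43 adhesion genes and 22 of 25 glutamate receptor genes were higher (adjusted p = 0.0946 for each with an estimated correlation). In Input 39 and 20 were (adjusted p = 0.126 and 0.104 with an estimated correlation). In pS6 Rab9b, a small GTPase gene, was at -1.98 ± 0.06 and Ly6c1, an endothelial gene, at 5.19 ± 0.13. In Input the 2 largest rises were those of Ly6c1 at 4.04 ± 0.06 and Sparc at 4.01 ± 0.06, and Apoe, an apolipoprotein gene of astrocytes, was at 3.81 ± 0.07. In total 4410 genes were higher and 1613 lower in Camk2a, 4520 and 1779 in pS6, and 3643 and 1478 in Input.

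The sleep comparison asks what sleep loss did to ribosome-bound and total RNA, set as SD minus Sleep over both training arms (14 SD and 16 Sleep mice). Immediate-early genes were among those that rose after SD. Fos rose by 1.43 ± 0.13 in cytosolic pS6 (adjusted p = 5.53e-09; above the Sleep median in 14 of 14 SD mice), by 0.86 ± 0.17 in cytosolic Camk2a and by 0.64 ± 0.10 in cytosolic Input. In cytosolic pS6 it stood at 15.6 ± 4.47 CPM in NoCFC Sleep (SD, n = 8), 42.9 ± 11.9 in NoCFC SD (SD, n = 7), 17.2 ± 3.45 in CFC Sleep (SD, n = 8) and 45.3 ± 9.26 in CFC SD (SD, n = 7). Hspa5, an ER chaperone gene, rose in all 6 library types, and Cirbp and Rbm3, which code for cold-inducible RNA-binding proteins, fell in 6 and 5 of the 6 types. Fos lies on chromosome 12, 85473890 to 85477273 (GRCm38).

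Of 47 activity-regulated genes, 33 rose and 1 fell in cytosolic pS6, and 35 and 1 when adjusted over the list alone (adjusted p = 5.53e-04 with an estimated correlation). There Fosb rose by 1.16 ± 0.12, Inhba by 1.09 ± 0.09, the orphan receptor gene Nr4a1 by 0.93 ± 0.07, Npas4 by 1.02 ± 0.17, the prohormone convertase gene Pcsk1 by 0.88 ± 0.11, Nptx2 by 0.68 ± 0.09 and Bdnf by 0.57 ± 0.06. In membrane pS6 22 rose and none fell (30 and 1 adjusted over the list alone), with Inhba at 1.05 ± 0.09, Pcsk1 at 0.85 ± 0.08, Npas4 at 0.88 ± 0.24 and Bdnf at 0.64 ± 0.06. In the Camk2a capture 15 rose and 2 fell in the cytosolic fraction (19 and 3 adjusted over the list alone), and 11 rose in the membrane fraction (18 and 3). Here Arc, a dendritic mRNA, rose by 0.41 ± 0.09 and 0.44 ± 0.09, Npas4 was at -0.14 ± 0.20 and 0.09 ± 0.18 without passing, and Bdnf was lower in the cytosolic fraction, at -0.17 ± 0.05 (adjusted p = 0.0389; lower in 13 of 14 SD mice). In Input 13 rose and 1 fell in the cytosolic and 7 rose and 1 fell in the membrane fraction. With an estimated correlation the list passed in all 6 types, with adjusted p of 0.028, 0.0258, 5.53e-04, 3.83e-04, 0.0247 and 0.0462 in Camk2a, pS6 and Input, cytosolic before membrane. The difference between captures in the SD effect was not tested.

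Genes of secreted peptides and of inhibitory neurons rose with SD in pS6. Of 28 neuropeptide and secreted-protein genes 14 rose and 1 fell in cytosolic pS6 (17 and 2 adjusted over the list alone; adjusted p = 0.0331 with an estimated correlation) and 12 rose in membrane pS6 (16 and 1; adjusted p = 0.0014). Crh, corticotropin-releasing hormone, rose by 1.04 ± 0.13 and 0.82 ± 0.10, Npy by 0.53 ± 0.08 and 0.47 ± 0.07, Scg2 by 0.50 ± 0.07 and 0.36 ± 0.05, and Vgf by 0.46 ± 0.08 and 0.42 ± 0.06. Of 24 inhibitory-neuron genes 16 rose in cytosolic pS6 (18 and 2 lower adjusted over the list alone; adjusted p = 0.00559 with an estimated correlation) and 9 in membrane pS6 (14; adjusted p = 3.55e-04). Sst, somatostatin, rose by 0.54 ± 0.10 and 0.47 ± 0.06 (in 14 of 14 and 14 of 14 SD mice), and Gad2, Lhx6, Dlx1 and Pvalb rose by 0.38, 0.34, 0.34 and 0.22 in cytosolic pS6. Kit and Lamp5 were at -0.18 ± 0.07 and -0.12 ± 0.05 there and did not pass. In cytosolic pS6 the mean log2 CPM of the list was higher in SD than in Sleep mice within each run. The difference was 0.24 in mice 1 to 11, 0.17 in mice 12 to 22 and 0.4 in mice 23 to 30. In Input none of the 24 passed in the cytosolic fraction (median -0.0091; camera adjusted p = 0.597) and 1 in the membrane fraction (median -0.028).

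Markers of other cells moved in the same libraries. The astrocyte list had a median of 0.34 in cytosolic pS6, where 1 of 23 genes passed, the connexin gene Gjb6 at 0.81 ± 0.22, and 0.2 in membrane pS6, where none did (adjusted p = 0.577 and 0.494 with an estimated correlation). Of 19 excitatory-neuron genes 5 fell in cytosolic pS6 (8 adjusted over the list alone; adjusted p = 0.141 with an estimated correlation) and 4 in membrane pS6 (10; adjusted p = 0.0252). Neurod6 was lower, at -0.15 ± 0.04 and -0.21 ± 0.05, as was Itpka, at -0.16 ± 0.05 and -0.21 ± 0.05. Of 11 CA1 genes 4 and 3 fell (adjusted p = 0.219 and 0.0252 with an estimated correlation), among them Fibcd1 at -0.31 ± 0.08 and -0.23 ± 0.05. Oligodendrocyte and microglial lists had medians of -0.019 and -0.044 in cytosolic pS6, with 1 and 0 genes past the test.

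Genes of ER chaperones and targets of stress hormones were among those that rose with SD. Of 26 ER chaperone genes 9 and 13 rose in Camk2a, 10 and 9 in pS6, and 9 and 11 in Input, cytosolic before membrane, and none fell. Adjusted over the list alone the numbers were 12, 15, 11, 16, 10 and 13, and the adjusted p with an estimated correlation was 0.474, 0.114, 0.281, 0.0282, 0.196 and 0.0269. Hspa5, the main ER chaperone, rose by 0.50 ± 0.09 in cytosolic and 0.57 ± 0.08 in membrane Camk2a and by 0.53 ± 0.07 in membrane Input, and Sdf2l1 rose by between 0.53 ± 0.09 in membrane Input and 0.85 ± 0.15 in cytosolic pS6. Manf, Creld2, Pdia4 and Xbp1 rose in all 6 types. Of the glucocorticoid targets 8 of 17 rose in cytosolic Input and 6 of 17 in membrane Input (13 and 11 adjusted over the list alone), and 4, 2, 6 and 5 of 16 in the captures, where 1 fell in cytosolic pS6. The list passed in all 6 types with an estimated correlation (adjusted p from 5.53e-04 to 0.0348). Sgk1, a kinase gene under glucocorticoid control, rose by 0.64 ± 0.09 and 0.78 ± 0.11 in Input and was at -0.02 ± 0.04 and 0.27 ± 0.10 in Camk2a, and Tsc22d3 rose by 0.65 ± 0.09 in membrane Input. Of the cytosolic heat-shock genes 5 of 19 rose in cytosolic Camk2a, including Chordc1 at 0.29 ± 0.06, and between 1 and 4 of 20 rose in the other types (adjusted p from 0.135 to 0.494 with an estimated correlation).

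Cirbp was lower, at -0.41 ± 0.05 in cytosolic Camk2a (lower in 14 of 14 SD mice), -0.49 ± 0.05 in membrane Camk2a and -0.38 ± 0.04 in cytosolic Input, and Rbm3 was lower, at -0.59 ± 0.07 in cytosolic Camk2a, and was at -0.28 ± 0.08 in membrane Input without passing. The pair passed as a list in all 6 types with an estimated correlation (adjusted p from 0.00175 to 0.0307). Of the clock genes 5 of 21 rose and 1 fell in cytosolic Camk2a, and 4 of 22 rose and 2 fell in cytosolic pS6 (adjusted p = 0.474 and 0.281 with an estimated correlation). Nfil3, a repressor of clock output, rose by 1.05 ± 0.08 in cytosolic pS6, Per1 by 0.42 ± 0.06, and Dbp was lower, at -0.31 ± 0.09. Among genes outside the lists, Wnt9a, a Wnt ligand gene (GRCm38, chromosome 11, 59306928 to 59333552), had the largest fall, at -1.17 ± 0.10 in cytosolic Camk2a (adjusted p = 8.86e-09; lower in 14 of 14 SD mice), -1.10 ± 0.11 in membrane Camk2a and -0.86 ± 0.07 in cytosolic Input. The splicing factor gene Srsf5 was lower, at -0.48 ± 0.05, and the deubiquitinase gene Usp2 at -0.49 ± 0.05 in cytosolic Camk2a, with Filip1 at -0.54 ± 0.08 and Bloc1s5 at -0.48 ± 0.05. Adamts2, Rsrp1, Dusp5 and Ackr3 rose there by 0.71, 0.63, 0.62 and 0.61. In cytosolic pS6 Alkal2 rose by 1.27 ± 0.12 and Cdkn1a by 1.09 ± 0.09, while Lefty2, Efcab6, Bhlha9 and Mamstr were lower, at -0.56, -0.52, -0.51 and -0.46. Ctgf rose by 0.87 ± 0.16 in membrane pS6, where Calhm2 was lower, at -0.49 ± 0.09, and Plekhf1 rose by 0.87 ± 0.10 in cytosolic Input. Rpl22 and Rps6, the genes of the captured proteins, passed in none of the 6 types. Neither did Camk2a, which lay between -0.19 and 0.03.

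Other lists are given for SD in cytosolic pS6, the type with the most genes past the test. There 4 of 34 synaptic vesicle genes rose and 1 fell, 4 of 43 chromatin modifiers, 3 of 20 cholesterol synthesis genes, 2 of 30 postsynaptic scaffold genes, 2 of 19 targets of the integrated stress response and 2 of 11 genes of oligodendrocyte precursors rose. In the same type 1 gene rose among 45 translation factors, 52 voltage-gated channels and 38 cytoskeletal genes each, 1 rose and 2 fell among 43 synaptic adhesion genes, 1 rose and 1 fell among 27 long noncoding RNAs and among 13 dentate granule genes, and 1 fell among 14 GABA receptors, 9 mitochondrial genes, 16 vascular and 14 choroid plexus genes each. No member passed among ribosomal proteins (46 large, 33 small), 75 oxidative phosphorylation genes, 16 glycolytic enzymes, 31 proteasome genes, 25 glutamate receptors, 13 genes of CA3 and CA2, 18 microglial and 5 blood genes. The camera adjusted p was 0.00148 for mitochondrial and 0.0243 for synaptic adhesion genes, both downward (0.577 and 0.947 with an estimated correlation), and ranged from 0.163 to 0.994 for the other lists of this paragraph.

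By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 622 genes rose and 321 fell in cytosolic Camk2a, 318 and 118 in membrane Camk2a, 753 and 546 in cytosolic pS6, 191 and 117 in membrane pS6, 336 and 190 in cytosolic Input, and 170 and 52 in membrane Input. Within mice 1 to 11, 12 to 22 and 23 to 30 taken alone, the numbers past the test were 34, 9 and 15 in cytosolic Camk2a, 34, 0 and 40 in membrane Camk2a, 77, 51 and 158 in cytosolic pS6, 15, 1 and 27 in membrane pS6, 8, 3 and 32 in cytosolic Input, and 3, 2 and 0 in membrane Input. For the counts of 0, 882 and 1167 genes had an unadjusted p under 0.05 by edgeR, the tool used within the runs. Genes past the test in mice 1 to 22 had, in mice 23 to 30, a slope between 0.809 and 1.09 and the same direction in 96.3% to 100% of cases. The real labels gave the highest slope of the 36 labelings of mice 23 to 30 in each type (exact permutation test, one-sided p = 0.0278, the smallest these mice allow), although genes are not independent replicates. With odd or even mouse number as a term, an alternative chosen after seeing the data, the totals rose from 943 to 1626 in cytosolic Camk2a and from 526 to 1032 in cytosolic Input. Without the low-count filter the total fell from 526 to 336 in cytosolic Input and rose from 308 to 664 in membrane pS6.

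**Figure D1:**
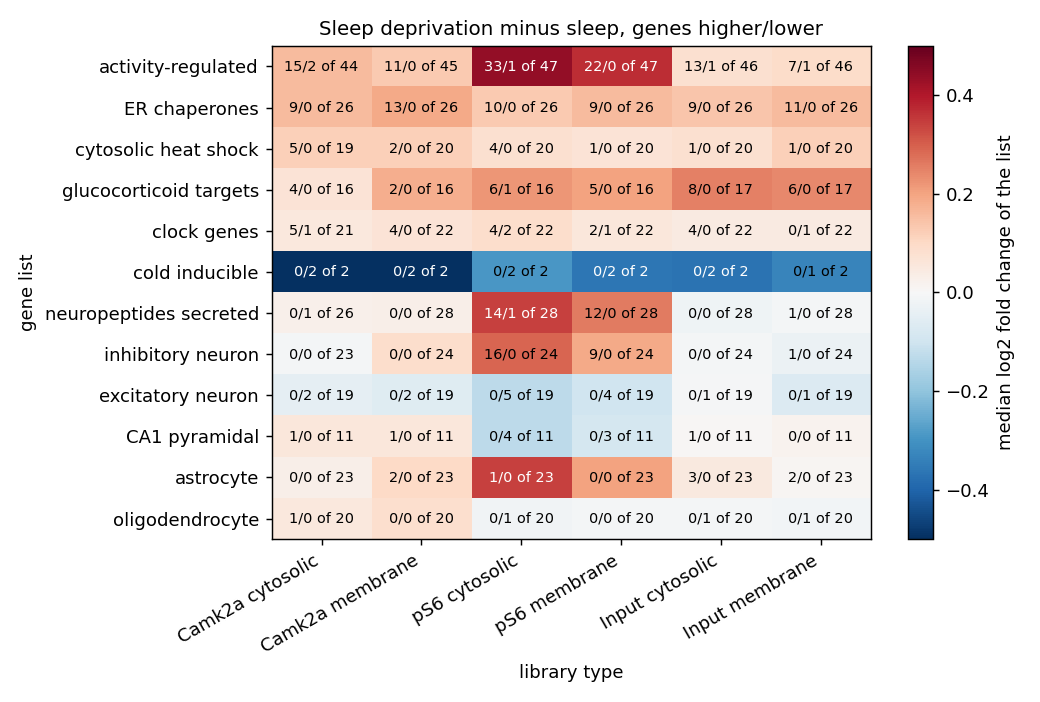
Median log2 fold change of SD minus Sleep (colour) for 12 gene lists in the 6 library types, with the number of genes higher and lower and the number tested written in each cell. The activity-regulated list reaches 33 higher of 47 in cytosolic pS6, and the inhibitory-neuron list 16 of 24 there against 0 of 24 in cytosolic Input.

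**Figure D2:**
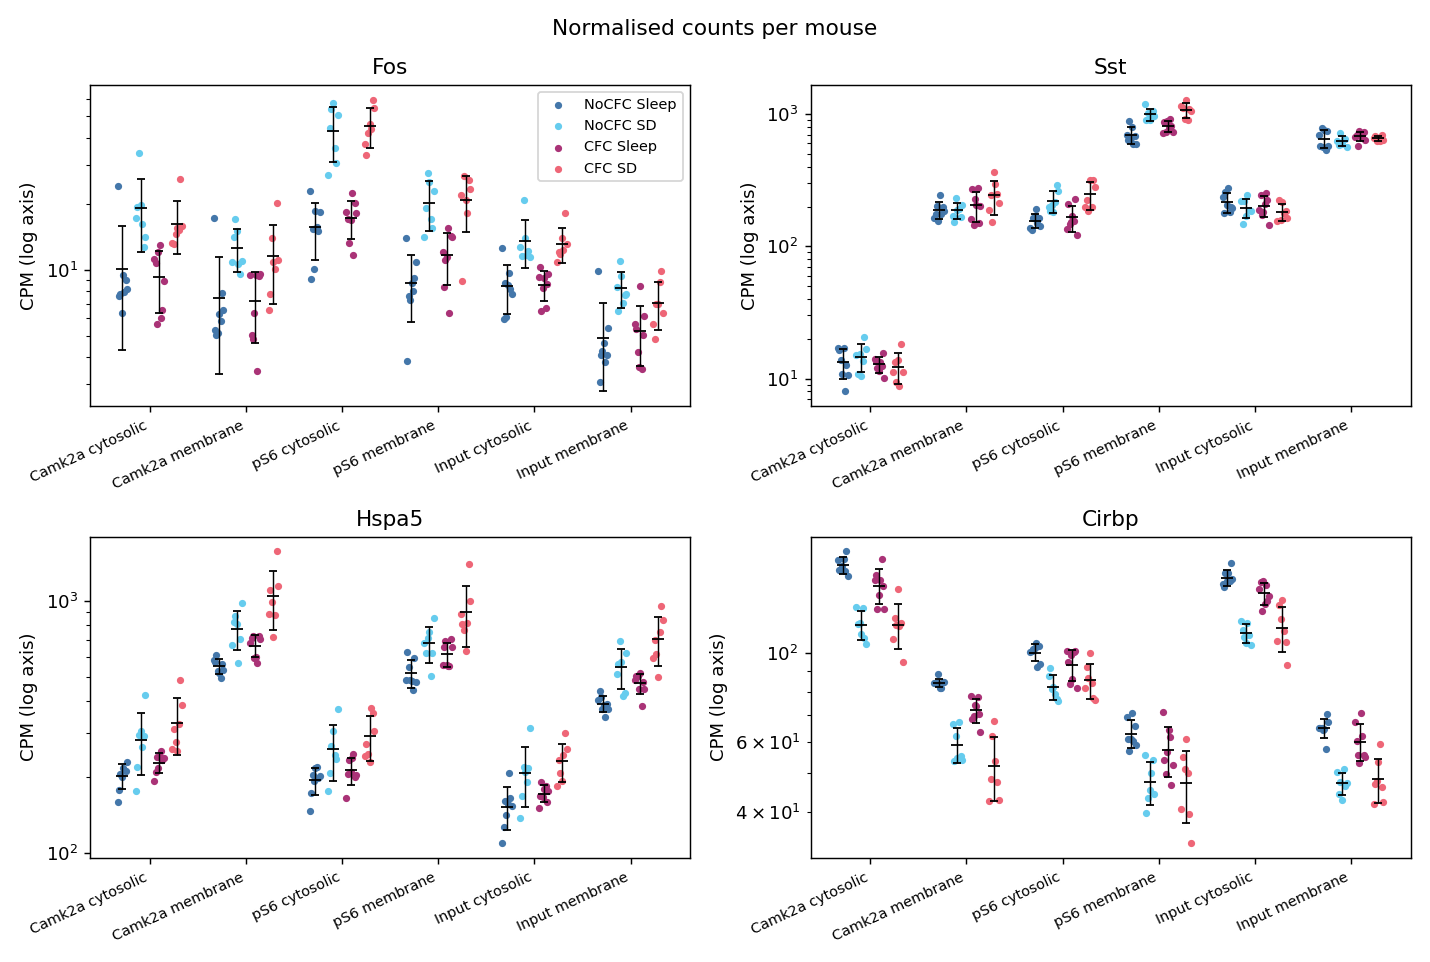
Normalised counts (CPM, log axis) of Fos, Sst, Hspa5 and Cirbp in each library type, one point per mouse, coloured by group, with the mean and SD of 8 or 7 mice as a bar. In cytosolic pS6 the means of Fos are 15.6 and 17.2 CPM in the Sleep groups and 42.9 and 45.3 CPM in the SD groups.

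The training comparison asks what fear conditioning changed, set as CFC minus NoCFC over both sleep arms (15 mice each). In cytosolic pS6 a small set of activity-regulated genes rose. Fosb rose by 0.95 ± 0.12 (adjusted p = 3.73e-05; higher in 15 of 15 CFC mice), from 12.6 ± 3.16 CPM (SD, n = 8) in NoCFC Sleep to 29 ± 3.7 CPM (SD, n = 8) in CFC Sleep. Egr3, a transcription factor gene, rose by 0.38 ± 0.05, Inhba by 0.47 ± 0.09, Atf3 by 0.56 ± 0.12, Fosl2 by 0.29 ± 0.06 and Errfi1 by 0.24 ± 0.05. That makes 6 of 47 activity-regulated genes (16 adjusted over the list alone; adjusted p = 0.0566 with an estimated correlation). Fos and Arc were at 0.11 ± 0.13 and 0.15 ± 0.10 and did not pass. Outside the list Cenpa rose by 0.53 ± 0.08, Spsb1 by 0.39 ± 0.07 and Maml2 by 0.43 ± 0.09, and Cpne8 was lower, at -0.19 ± 0.04.

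Fosb rose also within each part of the mice: in cytosolic pS6 it was at 0.88 ± 0.14 in mice 1 to 22 and at 1.05 ± 0.11 in mice 23 to 30 (adjusted p = 0.00131 by edgeR), and in membrane pS6 at 1.24 ± 0.18 in mice 23 to 30 (adjusted p = 0.0181). With the number run as a term, Fosb and Egr3 passed in cytosolic pS6 (adjusted p = 0.0293 for both), and Fosb, Nptx2 and Inhba in membrane pS6 (adjusted p = 0.00629, 0.0189 and 0.0487). In membrane pS6 without that term 11 of 47 activity-regulated genes rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 0.355 with an estimated correlation), with Fosb at 0.96 ± 0.12, Inhba at 0.63 ± 0.09, Nptx2 at 0.41 ± 0.06, Homer1 at 0.39 ± 0.07 and Bdnf at 0.34 ± 0.06. In cytosolic Camk2a 1 of 44 rose (4 and 1 lower adjusted over the list alone; adjusted p = 0.673 with an estimated correlation), and in membrane Camk2a 5 rose and 3 fell of 45 (adjusted p = 0.616).

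Glucocorticoid targets rose with training. In cytosolic Input 7 of 17 rose (11 adjusted over the list alone; adjusted p = 1.98e-04 with an estimated correlation), with Sgk1 at 0.50 ± 0.09, Tsc22d3 at 0.42 ± 0.06, Fkbp5, a glucocorticoid receptor co-chaperone gene, at 0.25 ± 0.05, Zbtb16 at 0.27 ± 0.04 and Plin4 at 1.49 ± 0.34. In cytosolic pS6 1 of 16 rose (8 adjusted over the list alone; adjusted p = 7.42e-05 with an estimated correlation), and in membrane Input 8 of 17 (10; adjusted p = 0.16). Sgk1 and Tsc22d3 in cytosolic Input were at 0.44 ± 0.12 and 0.39 ± 0.06 in mice 1 to 22 and at 0.58 ± 0.29 and 0.48 ± 0.10 in mice 23 to 30, where neither passed. The list rose in cytosolic Input with the number run as a term (camera adjusted p = 1.06e-12, and 0.0116 with an estimated correlation) and in cytosolic pS6 at the preset correlation alone (2.54e-05, and 0.0512 with an estimated correlation). Kif5a, a kinesin gene, was lower, at -0.28 ± 0.06 in cytosolic Input (0.0219 with the number run as a term, in the other direction), Sytl2 at -0.31 ± 0.06 and Sox2ot at -0.22 ± 0.05. In cytosolic Camk2a Pkp2 rose by 0.33 ± 0.06, Dhx33 by 0.32 ± 0.07 and Mkl1, a cofactor of serum response factor, by 0.26 ± 0.04, and Sh2d3c was lower, at -0.32 ± 0.06, and Id2 at -0.24 ± 0.05. No gene passed in cytosolic Camk2a or cytosolic Input by edgeR with the number run as a term. Over the 17 and 31 genes past the test in mice 1 to 22 in these types, the slope in mice 23 to 30 was -0.21 and 0.285, with the same direction in 52.9% and 61.3% of cases.

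In the membrane libraries the training groups differed in far more genes, but these libraries also differed by mouse number. By edgeR's test 1505 genes rose and 1094 fell in membrane Camk2a, 1414 and 1613 in membrane pS6, and 573 and 483 in membrane Input, against 19 and 3, 22 and 1, and 30 and 8 in the cytosolic libraries. Within mice 1 to 22, where run and training coincide, 2533, 3454 and 544 genes passed in the membrane types. Within mice 23 to 30, where both arms were present, 1, 4 and 0 passed, with 1444, 1449 and 1207 at an unadjusted p under 0.05. In the cytosolic types the numbers were 17, 9 and 31 in mice 1 to 22 and 0, 1 and 0 in mice 23 to 30, with 813, 873 and 811 at an unadjusted p under 0.05. With the number run as a term the totals were 0, 2 and 0 in the cytosolic and 1, 12 and 0 in the membrane types of Camk2a, pS6 and Input. NoCFC mice 23 to 30 differed from NoCFC mice 1 to 11 in 790 genes in membrane Camk2a, 513 in membrane pS6 and 14 in membrane Input. In the cytosolic types the numbers were 5, 79 and 0 (1493 at an unadjusted p under 0.05 in cytosolic Input). CFC mice 23 to 30 and CFC mice 12 to 22 differed in 0 genes in each type by edgeR, the tool used there (717 and 1717 at an unadjusted p under 0.05 in membrane Camk2a and pS6). The number of genes with a count in membrane Camk2a was 23426 ± 1227 in NoCFC mice 1 to 11 (SD, n = 11), 21945 ± 1155 in NoCFC mice 23 to 30 (SD, n = 4), 21027 ± 455 in CFC mice 12 to 22 (SD, n = 11) and 20739 ± 719 in CFC mice 23 to 30 (SD, n = 4). It was thus lower in CFC mice within numbers 23 to 30 too, which was not tested.

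No list in this paragraph or the next passed for CFC in the membrane types with an estimated correlation and without a run term. ER chaperones rose, 18 of 26 in Camk2a, 19 in pS6 and 14 in Input (22, 23 and 18 adjusted over the list alone; adjusted p = 0.251, 0.122 and 0.16 with an estimated correlation), and none rose in the cytosolic types, where the camera adjusted p was 0.00146, 0.175 and 0.0017. Hspa5 rose by 0.35 ± 0.08, 0.33 ± 0.09 and 0.32 ± 0.08, and in membrane Camk2a was at 0.26 ± 0.07 in mice 1 to 22 and 0.54 ± 0.11 in mice 23 to 30. With the number run as a term the list rose in all 3 membrane types (camera adjusted p = 2.78e-23, 2.00e-18 and 2.05e-18). With that term and an estimated correlation, an alternative chosen after seeing the data, the adjusted p was 0.0975, 0.0328 and 0.0489. GABA receptor genes rose, 6, 9 and 4 of 14 (8, 11 and 5 adjusted over the list alone; adjusted p = 0.391, 0.122 and 0.334 with an estimated correlation), and with the run term the camera adjusted p was 1.91e-05, 1.08e-11 and 6.23e-07 (0.293, 0.029 and 0.216 with an estimated correlation). Synaptic adhesion genes numbered 8 higher and 0 lower, 15 and 4, and 1 and 0 of 43 (adjusted p = 0.466, 0.492 and 0.856 with an estimated correlation). Of the long noncoding RNAs 10 fell and 1 rose of 27 in Camk2a, 9 and 4 of 28 in pS6, and 6 and 0 of 28 in Input (adjusted p = 0.251, 0.892 and 0.334 with an estimated correlation). In pS6 the median was 0.016 and the mean -0.23. The camera adjusted p with the run term was 0.687, 0.738 and 0.122. Meg3 was at -1.38 ± 0.19 in Camk2a and -1.20 ± 0.23 in pS6, and Snhg11, a gene of this list that the annotation types as protein-coding, at -1.39 ± 0.19 and -1.24 ± 0.25. Of genes outside the list, Dync1h1, a dynein motor gene, was at -1.56 ± 0.16 in pS6 and Leng8 at -1.03 ± 0.18 in pS6 and -0.92 ± 0.17 in Input. In mice 23 to 30 Dync1h1 was at -0.57 ± 0.13 in membrane pS6 and Malat1 at 0.01 ± 0.27 in membrane Camk2a, against -1.84 ± 0.12 and -1.53 ± 0.19 in mice 1 to 22.

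The counts of list genes in this paragraph come from the fit without the run term, so differences between number runs can enter them. Cytoskeletal genes fell, 21 of 38 in Camk2a, 24 in pS6 and 7 in Input, with 3, 2 and 0 higher (adjusted p = 0.251, 0.122 and 0.243 with an estimated correlation), and Sptan1, a spectrin gene, was at -0.44 ± 0.09 and -0.85 ± 0.14. Chromatin modifiers fell, 12, 23 and 10 of 43, and postsynaptic scaffold genes, 12, 17 and 4 of 30 (adjusted p = 0.277, 0.122 and 0.243, and 0.251, 0.16 and 0.296 with an estimated correlation). Proteasome genes fell, 17, 6 and 0 of 31 (adjusted p = 0.251, 0.301 and 0.856). Markers of glia moved with these groups in membrane Camk2a: 14 of 23 astrocyte genes rose (median 0.34; adjusted p = 0.264 with an estimated correlation), 11 of 19 microglial genes (median 0.36; 0.31), 8 of 20 oligodendrocyte genes (median 0.32; 0.433) and 4 of 11 precursor genes (median 0.31; 0.371). Etnppl and Mertk, genes of astrocytes, rose by 0.85 ± 0.13 and 0.80 ± 0.13, Sdc4 by 0.82 ± 0.12, and Ptgds by 0.84 ± 0.25 (-0.15 with the number run as a term, in the other direction). In membrane pS6 2 astrocyte and 6 microglial genes rose and in membrane Input 6 of each, with 1 astrocyte gene lower.

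**Figure D3:**
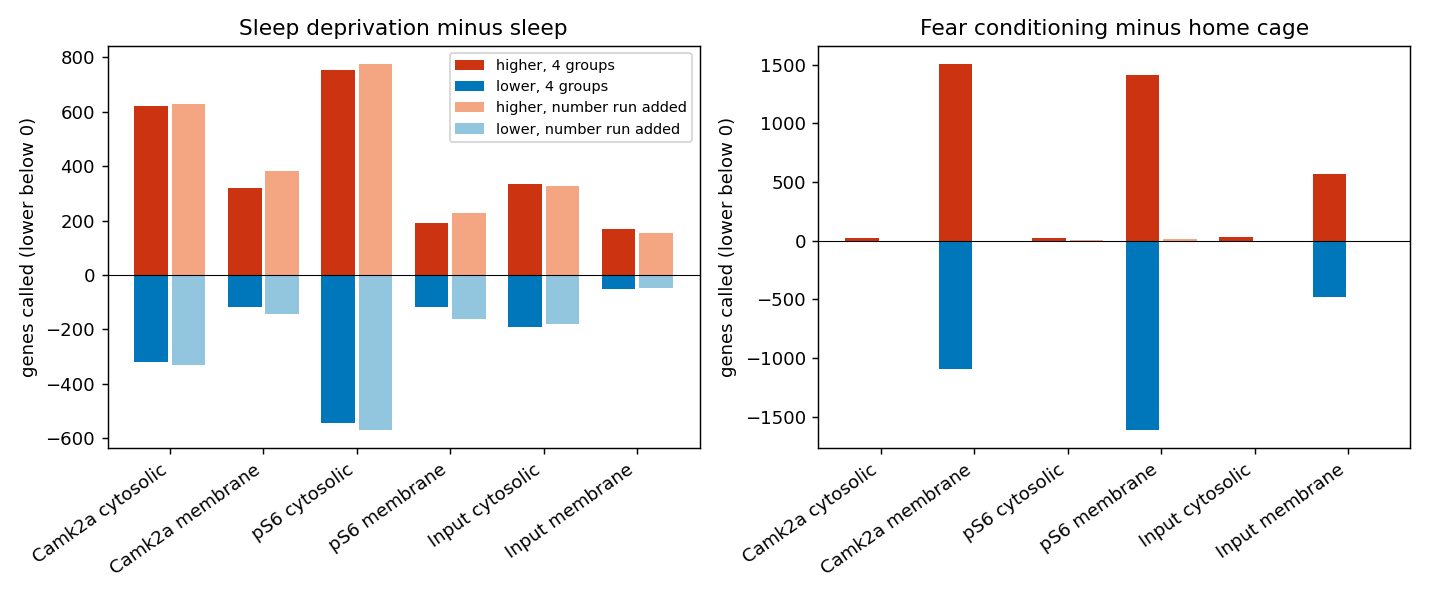
Number of genes higher (above 0) and lower (below 0) past the test for SD minus Sleep and for CFC minus NoCFC in each library type, with the 4 groups alone (dark) and with the number run added as a term (light). The membrane bars for CFC shrink from 2599, 3027 and 1056 genes to 1, 12 and 0. The SD bars keep their height within a factor of 1.5. The design favours this contrast, since every run held SD and Sleep mice but only the last held both CFC and NoCFC mice. In simulated membrane Camk2a data the run term lowered the recovery of 1.5-fold changes from 91% to 55.2% for CFC. For SD it stayed at 83.6%. How much of the shrinkage is lost power was not tested.

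**Figure D4:**
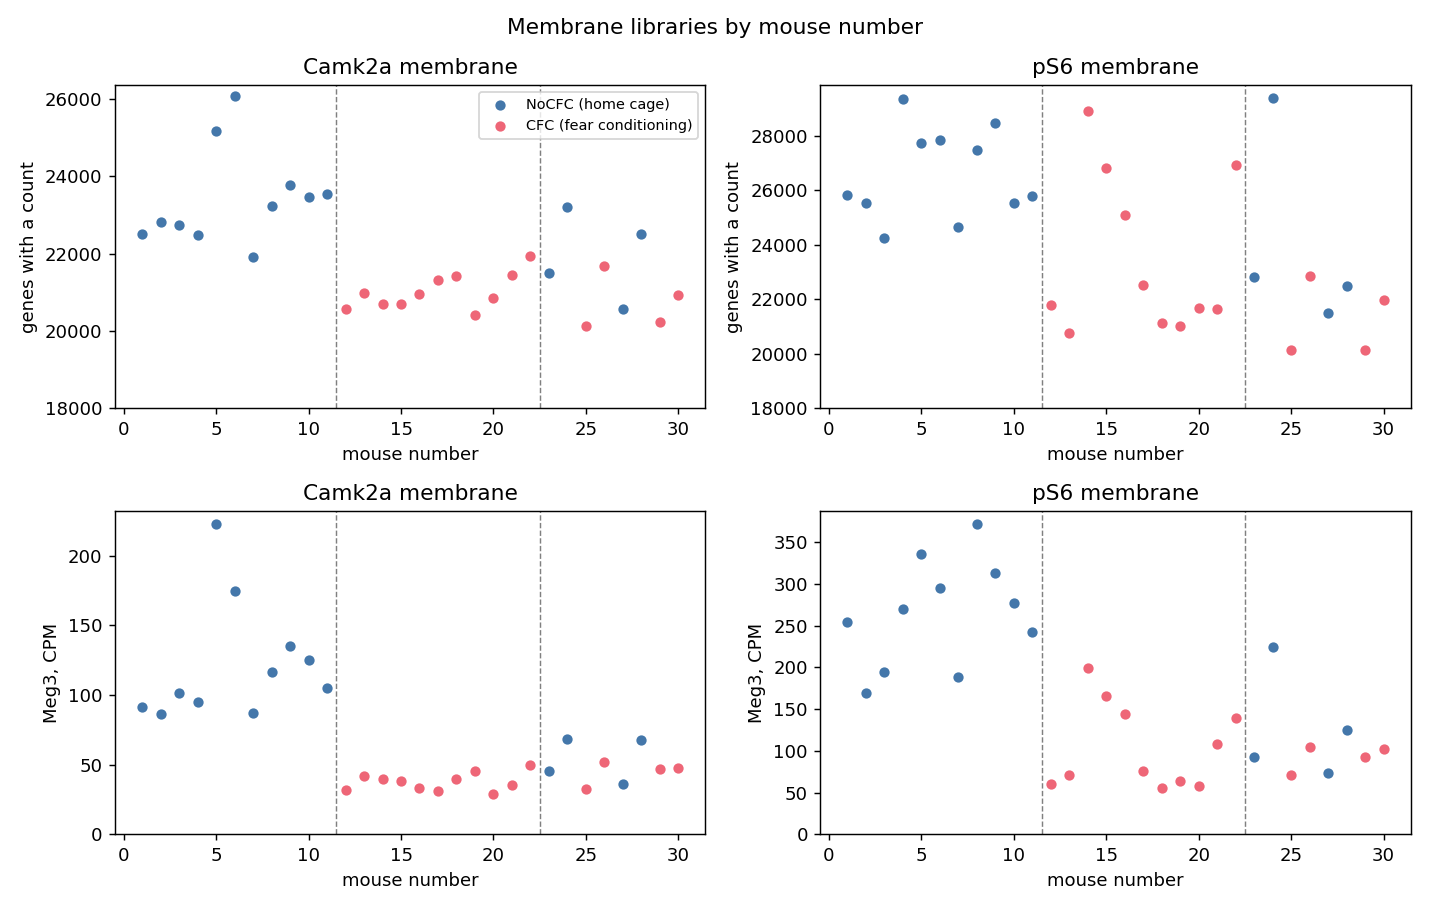
Genes with a count and the normalised count of Meg3 (CPM) in the membrane Camk2a and pS6 libraries, one point per mouse against mouse number, with dashed lines between the number runs and colour for training. In membrane Camk2a mice 1 to 11 hold 23426 ± 1227 genes with a count and mice 12 to 22 hold 21027 ± 455 (SD, n = 11 each).

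The interaction of training with sleep asks whether sleep loss acted differently after learning. No gene passed in any of the 6 types by edgeR (324, 717, 725, 747, 420 and 456 genes at an unadjusted p under 0.05, in Camk2a, pS6 and Input, cytosolic before membrane), nor by DESeq2 or limma-voom. At that threshold chance alone gives 742, 748, 824, 832, 797 and 782 genes, more than were seen in each type. Such a shortfall, as in cytosolic Camk2a and both Input types, points to a conservative test. The lack of calls therefore does not show that the effects of training and sleep loss simply add. Fos, for one, rose with SD in both arms of cytosolic pS6, as its means above show. Without the low-count filter 104, 274 and 158 genes passed in membrane Camk2a and both pS6 types, and with the number run as a term 1 passed in cytosolic Input. Taken arm by arm, SD changed 188 genes in NoCFC and 193 in CFC in cytosolic Camk2a, 74 and 123 in membrane Camk2a, 417 and 373 in cytosolic pS6, and 30 and 67 in membrane pS6. CFC changed 1 gene in Sleep and 0 in SD in cytosolic Camk2a (672 in SD at an unadjusted p under 0.05 by edgeR, against 742 expected by chance, and 2 by DESeq2 and 1 by limma-voom), 156 and 1241 in membrane Camk2a, 3 and 4 in cytosolic pS6, and 1070 and 939 in membrane pS6. Without mouse 22, whose libraries stand apart in 3 types, the 156 became 288 and the 4 became 2. With the number run as a term CFC changed 1 gene in each arm of membrane Camk2a. In Sleep and in SD it then changed 1 and 0 in cytosolic pS6, and 5 and 1 in membrane pS6.

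The interaction of fraction with the conditions asks whether transcripts moved between fractions. For SD no gene passed in Camk2a or pS6 by edgeR (394 and 919 at an unadjusted p under 0.05, against 789 and 893 expected by chance) or by DESeq2. In Camk2a that is fewer than chance gives, so the lack of calls there does not show that SD acted alike in both fractions. In pS6 1 gene passed by limma-voom and 1 with the mouse as a block. Fos, Hspa5 and Cirbp were among the genes that did not pass. For CFC 89 genes were higher and 95 lower in the membrane relative to the cytosolic fraction in Camk2a, and 325 and 422 in pS6, and with the mouse as a block 433 and 511, and 578 and 773. Tsc22d3 was at 0.51 ± 0.08 and Paqr8 at 0.49 ± 0.09 in Camk2a, against Snhg11 at -1.35 ± 0.20 and Dync1h1 at -0.77 ± 0.12. In pS6 Ids was at 0.45 ± 0.08, Ppargc1b at -0.85 ± 0.12, Snrnp70 at -0.61 ± 0.10 and Leng8 at -1.14 ± 0.19. The split depended on scaling: 48.4% and 43.5% of the genes were higher, but 84.1% and 76.1% with RLE normalization and 86.4% and 78.3% with DESeq2. A fit with the number run and its interaction with fraction as terms was added after seeing the data. It estimates CFC from mice 23 to 30 alone. By edgeR 0 genes passed in it for CFC in Camk2a and in pS6 (1293 and 1456 at an unadjusted p under 0.05).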

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

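The tests of number runs, of odd and even numbers by library type, of the inhibitory-neuron genes and of other splits were chosen only after the results were seen, and that of membrane purity before.

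Of 120 groups and measures of library quality 12 held a library that stood apart, where chance gives about 6. Mouse 22, a CFC SD mouse, stood apart in 3: 26916 genes with a count in membrane pS6 (others 20143 to 21988), and a distance to the other libraries of 0.457 in membrane Camk2a (others 0.336 to 0.357) and of 0.546 in cytosolic pS6 (others 0.336 to 0.42). Mouse 12 had 24 M counts in membrane Input (others of its group 13.8 to 17.8 M) and 6.91% of counts in the 10 most abundant genes of membrane pS6 (others 5.51% to 5.97%). Mouse 4 had 0.0203% mitochondrial counts in cytosolic Camk2a (others 0.0108% to 0.0143%) and 0.061% in cytosolic pS6 (others 0.0322% to 0.0446%). Mouse 7 had 7.24% in the 10 most abundant genes of membrane pS6 (others 5.56% to 6.25%) and a distance of 0.313 in cytosolic Input (others 0.257 to 0.278). Mouse 19 had 7.92% in the 10 most abundant genes of membrane pS6 (others 5.51% to 6.42%). Mouse 2 had 23536 genes with a count in cytosolic pS6 (others 22023 to 22663), and mouse 6 a distance of 0.382 in cytosolic Input (others 0.262 to 0.316). The effect of CFC differed between the fractions in 184 genes in Camk2a and 747 in pS6 by the interaction test, and in 0 of each by edgeR with the number run by fraction as a term (1293 and 1456 at an unadjusted p under 0.05).

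CFC calls in the membrane libraries, 2599 in Camk2a, 3027 in pS6 and 1056 in Input, may follow from differences between number runs: over the genes past the test in mice 1 to 22, the slope in mice 23 to 30 was 0.203, 0.233 and 0.187. The direction was the same in 76.1%, 69.5% and 82.9% of them. Of the 36 labelings of mice 23 to 30, 4, 3 and 3 gave as high a slope (exact permutation test, one-sided p = 0.111, 0.0833 and 0.0833). In Input NoCFC mice 23 to 30 differed from NoCFC mice 1 to 11 in 14 genes, against 790 and 513 in Camk2a and pS6. Training at the size seen in mice 1 to 22 is argued against, since the highest of these slopes with its spread reached 0.552, short of 1. Purity of the membrane fraction stays open: across called genes, which are not independent replicates, the CFC change correlated with the membrane against cytosolic change at 0.524 in Camk2a, 0.282 in pS6 and 0.417 in Input. Training and run coincide in mice 1 to 22, so a smaller effect of training and the run cannot be told apart there.

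Odd and even mouse numbers differed in 6040 genes in cytosolic Camk2a, 3668 in membrane Camk2a, 3361 in cytosolic pS6, 505 in membrane pS6, 6549 in cytosolic Input and 3309 in membrane Input, among genes with a known GC content, and no biological explanation was tested. GC content as the whole cause is argued against in cytosolic Camk2a, where 71.2% of the calls were left after its correction. It stays open in membrane Camk2a (30.7%), cytosolic pS6 (24.2%), membrane pS6 (27.7%) and cytosolic Input (44.1%), and is consistent with the calls in membrane Input (8.55%). Transcript length left 36.2% in membrane pS6 and stays open there. It left 80.6%, 71.7%, 74.6%, 88.6% and 97.4% in the other 5 types, and is argued against as the whole cause in them. Library size is argued against as well, with 98.1%, 88.5%, 101%, 100% and 65% left in the first 5 types. In membrane Input it left 23.1% and stays open, with 19.2 M counts on average in even and 14.8 M in odd numbers. These tests were first planned over all types at once, where GC content and library size stayed undecided and length was argued against, and were split by type after that. Membrane pS6, which had the fewest calls, was added last.

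The rise of inhibitory-neuron genes with SD in pS6 may reflect more pS6-bearing ribosomes in those neurons, a hypothesis that was not tested. A lower share of excitatory neurons in the capture would raise glial markers alike, but the glial lists were split. Oligodendrocyte and microglial medians lay below the inhibitory-neuron median, which goes against it, with a smallest gap of -0.2 (gaps of -0.31 ± 0.078 and -0.34 ± 0.062 in cytosolic and -0.2 ± 0.061 and -0.23 ± 0.055 in membrane pS6). The astrocyte median moved with the inhibitory-neuron median (gaps of 0.05 ± 0.065 and 0.0084 ± 0.062), which goes with it. The excitatory-neuron median was -0.13 in cytosolic and -0.1 in membrane pS6. A lower share of excitatory neurons therefore stays open. More inhibitory-neuron RNA in the tissue is argued against by medians of -0.0091 and -0.028 in Input.

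Other splits of the mice were compared for 47 results, and for 37 fewer than 5% of the splits gave as many genes. The median of the other splits was 0 genes, so very small counts meet this rule too. For SD, 1 of 100 splits, the real one, gave as many genes in each of the 6 types: 943 against a highest other of 3, 436 against 280, 1299 against 10, 308 against 2, 526 against 1 and 222 against 4. For SD within NoCFC and within CFC in cytosolic Camk2a 2 of 100 did (188 against 465 and 193 against 791), and in membrane Camk2a, cytosolic pS6 and membrane pS6 1 did (74 against 38 and 123 against 4, 417 against 122 and 373 against 91, 30 against 5 and 67 against 2). For CFC the real split was highest in 5 types, with 22 against 1, 2599 against 296, 3027 against 90, 38 against 16 and 1056 against 148, and in cytosolic pS6 2 of 100 gave as many, 23 against 63. For CFC within Sleep 2 of 100 gave as many in cytosolic Camk2a (1 against 490), and 1 in the others (156, 3 and 1070 against 1 each). Chance is not excluded for the gene called in cytosolic Camk2a, a call lost with limma-voom and with the run term. For CFC within SD the counts were 1241 against 345 in membrane Camk2a and 939 against 7 in membrane pS6, whereas in cytosolic Camk2a 100 of 100 splits gave as many as 0 (highest 1093) and in cytosolic pS6 5 of 100 gave as many as 4 (highest 818), so chance cannot be excluded there. The training by sleep interaction, at 0, was reached by 100 of 100 splits in each type (highest 1, 1, 154, 7, 1 and 1), as was fraction by SD (highest 1 and 2), and chance cannot be excluded for these. Some of these splits called several times the real count, which points to a structure of the samples. Those with 1093, 818 and 791 genes differed between their groups by 71.4%, 71.4% and 73.2% in the share of even numbers and that with 490 by 50%. Those with 465, 154 and 63 differed by 19.6%, 13.4% and 20%. For the 154, an interaction, this gap pools both training arms and does not measure odd and even numbers within each. Odd and even numbers are thus not shown to account for all of them. Fraction by CFC had 184 against 2 and 747 against 1. The splits for CFC broke up the number runs, so they cannot exclude a difference between runs. For the fractions the real split was highest of 50, with 6023 against 3, 6299 against 0 and 5121 against 0, and for the captures with 2773 against 2 and 3006 against 0 (Camk2a against Input), 3471 against 0 and 1857 against 1 (pS6 against Input), and 5127 against 34 and 3030 against 5 (pS6 against Camk2a). In these other splits the 2 libraries of 15 mice traded places, so each group held both kinds equally. Few calls were bound to follow, so the fraction and capture results among the 37 draw no support from them.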

How the results depend on the processing

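The odd or even number term, the number run by fraction term, the run term with an estimated correlation for lists and the fit without mouse 22 were chosen only after the results were seen. Named genes with an adjusted p under 0.05 in the main fit were followed, each gene counted once per result. In fraction and capture comparisons these include genes short of the fold of 2, which counted as kept where they fell short in both fits. Many named genes were picked for their large change, which favours high shares. The call with its direction, or the lack of a call, was kept for 1323 of 1341 with DESeq2, 1321 of 1342 with RLE, 1324 of 1342 with limma-voom, 1300 of 1342 without the low-count filter, 936 of 941 with the mouse as a block, 239 of 401 with the run term, 0 of 24 with the number run by fraction term, 400 of 401 with the odd or even term and 390 of 401 without mouse 22. Counts of genes stayed within 1.5 times in 30 of 47 results with DESeq2, 46 with RLE, 36 with limma-voom, 18 without filter, 10 of 13 with the block, 19 of 34 with the run term, 2 of 4 with the number run by fraction term, 24 of 34 with the odd or even term and 32 of 34 without mouse 22. For each change below the cause was not tested, except that without a filter more genes were tested. Depth limits the calls among genes with few counts.

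With the odd or even term the SD count rose from 943 to 1626 in cytosolic Camk2a and from 526 to 1032 in cytosolic Input, and the CFC count from 22 to 43 and from 38 to 77. SD in NoCFC and in CFC went from 188 and 193 to 507 and 562 in cytosolic Camk2a and from 74 and 123 to 113 and 191 in membrane Camk2a. CFC in Sleep went from 1 to 9 in cytosolic and from 156 to 412 in membrane Camk2a. Without mouse 22 CFC in Sleep in membrane Camk2a was 288, and CFC in SD in cytosolic pS6 was 2.

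With DESeq2 CFC called 57 genes in cytosolic Camk2a, 55 in cytosolic pS6 and 79 in cytosolic Input, and SD 468 in membrane pS6. SD in NoCFC and in CFC called 336 and 384 in cytosolic Camk2a, 141 and 207 in membrane Camk2a, and 81 and 117 in membrane pS6. CFC in Sleep and in SD called 11 and 2 in cytosolic Camk2a and 16 and 11 in cytosolic pS6, and CFC in Sleep 392 in membrane Camk2a. Fraction by CFC called 734 in Camk2a and 1455 in pS6. RLE moved fraction by CFC in Camk2a to 345.

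With limma-voom CFC called 73 in cytosolic Camk2a and 74 in cytosolic Input. SD in CFC called 409 in cytosolic and 205 in membrane Camk2a, and SD in NoCFC 67 in membrane pS6. CFC in Sleep called 0 in cytosolic Camk2a, 690 in membrane Camk2a and 1611 in membrane pS6, and CFC in SD 1 in cytosolic Camk2a. Fraction by CFC called 511 in Camk2a and fraction by SD 1 in pS6. With the mouse as a block fraction by CFC called 944 and 1351, and fraction by SD 1 in pS6. No other count moved beyond 1.5 times with the block.

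With the run term CFC called 0, 1, 2, 12, 0 and 0 genes in the 6 types, CFC in Sleep 0 and 1 in cytosolic and membrane Camk2a and 1 and 5 in pS6, and CFC in SD 1 in membrane Camk2a, 0 in cytosolic pS6 and 1 in membrane pS6. SD in NoCFC called 48 in membrane pS6, and training by sleep 1 in cytosolic Input. Reversal was looked at in named genes alone. Of all genes called for CFC in mice 1 to 22, 76.1%, 69.5% and 82.9% kept their direction in mice 23 to 30. These are the shares in membrane Camk2a, pS6 and Input. Among the named genes the CFC effect reversed for 11, none of which passed. In membrane Camk2a these were Malat1 at 0.0101, Miat at 0.047, Ptgds at -0.15, Sult1a1 at -0.041 and Tshz2 at 0.18. In membrane pS6 they were F3 at -0.0183, Gad1 at 0.047, Pclo at 0.0162 and Tubb3 at 0.0583. In cytosolic Input it was Kif5a at 0.0219, and in membrane Input Sptan1 at 0.0443. With the number run by fraction term fraction by CFC called 0 in both captures. The cytoskeleton list for CFC in cytosolic pS6 and the vascular list in cytosolic Input reversed as well (camera adjusted p = 4.34e-04 and 8.78e-04).

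Without the low-count filter training by sleep called 104 genes in membrane Camk2a, 274 in cytosolic pS6 and 158 in membrane pS6, and fraction by SD 1 in Camk2a and 4 in pS6. SD called 664 in membrane pS6 and 336 in cytosolic Input, and CFC 218 in cytosolic pS6 and 23 in cytosolic Input. SD in NoCFC and in CFC called 127 and 386 in membrane Camk2a and 215 and 457 in membrane pS6, and SD in CFC 950 in cytosolic pS6. CFC in Sleep called 4 in cytosolic and 855 in membrane Camk2a and 95 in cytosolic pS6, and CFC in SD 417 in cytosolic and 1520 in membrane pS6. Membrane against cytosolic called 9464 in Camk2a and 11315 in pS6, and fraction by CFC 459 and 1200. Camk2a against Input called 6451 in the cytosolic and 5602 in the membrane fraction, pS6 against Input 6193 and 6099, and pS6 against Camk2a 8121 and 6571.

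The share of higher genes moved by more than 10 points in the cases below. Left out are those where one of the 2 counts was 0 and CFC with the run term, which left at most 12 genes. With DESeq2 it went from 95.7% to 83.6% for CFC in cytosolic pS6, from 78.9% to 68.4% for CFC in cytosolic Input, from 93.3% to 72.8% for SD in NoCFC in membrane pS6. For fraction by CFC it went from 48.4% and 43.5% to 86.4% and 78.3%, and with RLE to 84.1% and 76.1%. With limma-voom it went to 67.6% for CFC in cytosolic Input and 73.1% for SD in NoCFC in membrane pS6. It also went from 53.8% to 65.1% for CFC in Sleep in membrane Camk2a and from 66.3% to 53.8% for pS6 against Input in the membrane fraction. Without the filter it went to 80.7% for CFC in cytosolic pS6, from 100% to 49.5% and 86.3% for CFC in Sleep and in SD there. It went from 71.6% and 71.5% to 57.5% and 84.5% for SD in NoCFC and in CFC in membrane Camk2a, and from 65.4% to 76.1% for CFC in SD there. It was 63.7% for SD in NoCFC in membrane pS6, 67.5% and 80.4% for fraction by CFC, and 84.2% for pS6 against Input in the membrane fraction. With the run term it was 81.2% for SD in NoCFC in membrane pS6, and without mouse 22 it was 64.9% for CFC in Sleep in membrane Camk2a.

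Gene lists past the camera test numbered 367 over all results, 36 with an estimated correlation, 377 with the run term and 46 with both.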

Other observations

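The values here were chosen only after the results were seen, and no test was made on them. In cytosolic Camk2a libraries the first principal component of log CPM followed odd or even mouse number with an r-squared of 0.757, and in cytosolic Input with 0.733. In membrane Camk2a and membrane pS6 its r-squared was 0.449 and 0.506 with the number run and 0.37 and 0.406 with training, which coincide in mice 1 to 22. Genes with a count in membrane pS6 fell from 26584 ± 1659 in NoCFC mice 1 to 11 (SD, n = 11) and 24050 ± 3603 in NoCFC mice 23 to 30 (SD, n = 4) to 23476 ± 2901 in CFC mice 12 to 22 (SD, n = 11) and 21284 ± 1370 in CFC mice 23 to 30 (SD, n = 4).

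Mitochondrially encoded RNA took 0.014% of counts in cytosolic and 0.978% in membrane Camk2a, 0.0416% and 1.15% in pS6, and 0.978% and 7.29% in Input, averaged over 30 libraries in each type.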
